A study of Rattus norvegicus with 125 samples.

How the data were processed

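Expression was measured on Affymetrix rat arrays in brain, heart, kidney, liver and lung of adult male Sprague-Dawley rats after a whole-body exposure to phosphine (PH3) or air. RNA came from frozen, powdered tissue and was labelled by a 3' method. The deposited values cover 31139 probe sets on 125 arrays from 48 rats, counted by the numbers in the labels. At 6 h the labels give PH3 rat 135 in brain only and PH3 rat 134 in heart, kidney and liver, and they were taken as 2 rats. Per the labels, the authors summarised the arrays by RMA, a method that corrects background, normalises by quantiles and combines the probes of a set, and the deposited values are on the log2 scale. The submitters' processing notes name RMA, Affymetrix Expression Console and Partek without versions. The values ran from 2.60 to 14.41, and the array medians from 5.08 to 5.52. Arrays have no read depth, so the number of arrays sets the precision of each value. Blood, which the series text mentions, was not analysed here.

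Probe sets were paired with genes through the platform annotation. Of the probe sets, 19068 had 1 gene symbol, 573 had several and 11498 had none. Gene identifiers of 18989 probe sets matched the RefSeq gene table of GRCr8, and 0 symbols had to be updated. Each of 13438 genes was represented by its probe set with the highest mean over all arrays of the tissue. No coordinates are given. Probe sets without 1 gene name were tested apart.

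Groups were defined by tissue, exposure and time after exposure, which gave 33 groups and 16 comparisons of PH3 with Air. The 3 PH3 arrays of liver at 3 h have no Air counterpart and entered the liver fit without a comparison. For each tissue, limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group over all arrays of the tissue, so that groups of 2 to 4 arrays shared an estimate of the spread. Moderated statistics came from eBayes with a trend in the mean, and p-values were adjusted by Benjamini and Hochberg within each comparison, with 0.05 as the threshold. A limma F test asked whether the exposure effect differed between the times of a tissue. A further F test asked whether it differed between brain, heart and kidney at 1, 3 and 6 h. These tissues came mostly from the same rats, so that test was repeated with the rat as a block. Values were read with data.table version 1.17.8, and the plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

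The 57 gene lists cover stress responses, metabolism, cell types, and regions of the brain, and they were written from general knowledge before the data were examined. A list was tested where it suited the tissue and at least 4 members were measured. The test was camera in limma with a preset correlation of 0.01 between genes, adjusted over all 692 tests together. Camera with an estimated correlation and fry were run beside it. Camera asks whether the members changed more than other genes, and fry whether they changed at all. List members were counted at an adjusted p under 0.05 over all genes and, separately, adjusted over the list alone. A change in a list is given as the median log2 change of its members.

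The genes named for each comparison were chosen by a rule fixed before the data were examined. It takes up to 8 genes with the largest rise and up to 8 with the largest fall among those that passed and whose PH3 and Air arrays did not overlap. It also takes up to 4 passing members of each list and a fixed panel of stress and injury genes. Where fewer than 3 genes passed, it takes the 3 genes with the smallest unadjusted p. Other list members and the genes named for differences between times or tissues were chosen after their values were seen.

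Array quality was compared between PH3 and Air by 48 two-sided permutation tests of the 3' to 5' signal of beta-actin and GAPDH and of the correlation within groups. The smallest adjusted p was 0.343, and with 4 against 4 arrays an exact p cannot fall below 0.0286. That p was reached in 4 tests, all of the correlation within the group. The correlations were computed in the real groups and not anew for each permutation, and arrays of a group share pairs. For this measure the p-values are therefore not exact and do not test a difference in spread. The correlation was lower in PH3 than in Air in heart at 1 h (0.981 against 0.988), kidney at 3 h (0.972 against 0.987) and liver at 6 h (0.986 against 0.989), and higher in lung at 24 h (0.986 against 0.973). In brain at 1 h the 3' to 5' difference was higher in PH3 for both genes, by 0.512 for beta-actin and 0.505 for GAPDH (exact p = 0.0857, adjusted p = 0.457). Any 2 arrays of a group correlated at 0.951 to 0.994, with a median of 0.986, and 0 columns were identical.

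The fits were tested on simulated data with 200 of 13438 genes changed, raised and lowered in turn. The simulated noise was normal and independent between genes and arrays, without the structure that real arrays of a group share. The shares recovered therefore need not hold for the real data. With the spread of heart at 6 h, 45.5% of genes changed 1.5-fold, 85.5% of those changed 2-fold and 99.5% of those changed 4-fold were recovered. With the 2 Air and 4 PH3 arrays of lung at 3 h, the shares were 22.5%, 59.5% and 95%. With the spread of brain at 1 h they were 58%, 89% and 98%. The test between times recovered 64% of genes changed 2-fold at 6 h in heart and 75% at 1 h in brain. Camera called the 1 list of 20 genes raised 1.5-fold in simulated heart at 6 h, and 0 of 20 unchanged lists.

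Alternatives fixed before the data were examined were a fit on the compared groups alone, all probe sets instead of 1 per gene, dropping the third of genes with the lowest mean, a further quantile normalization, limma array weights, the other probe sets of each named gene, and leaving out each array in turn. Alternatives without arrays that stood apart were chosen after seeing the data. The samples of each comparison of at least 3 against 3 arrays were also split in every other way of the same sizes, or in at most 100 drawn ways.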

Results

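Gene expression was compared on 125 arrays from 48 adult male rats that had breathed air or phosphine, a fumigant gas that inhibits cytochrome c oxidase, the last complex of the mitochondrial respiratory chain. Phosphine was given at 387 ppm for 40 min, a product of 15480 ppm×min. Brain gave 32 arrays, heart 29, kidney 32, liver 11 and lung 21. Brain, heart and kidney were sampled 1, 3, 6 and 24 h after exposure, liver at 3 and 6 h, and lung at 3 h, 24 h and 1 week. Groups held 4 rats, except for 2 Air rats in heart at 24 h and lung at 3 h, and 3 PH3 rats in heart at 24 h, liver at 3 h and lung at 1 week. Below, levels are mean log2 signals ± SD, and changes are log2 differences of PH3 minus Air ± the standard error of the limma fit.

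The 16 comparisons ask which genes responded to the gas in each organ, and when. Of 13438 genes, 506 changed in at least 1 comparison, 26 in at least 2 and 19 in at least 2 tissues. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, rose in heart at 1 and 3 h, kidney at 3 h and lung at 3 h. Errfi1, an inhibitor of the EGF receptor, rose in kidney at 1, 3 and 24 h and in lung at 3 h. Tnfrsf12a, the receptor of the cytokine TWEAK, rose in kidney at 1, 3 and 6 h and in heart at 6 h. Metallothionein Mt2A rose in brain and heart at 6 h. Glucocorticoid targets as a list were higher in 15 of the 16 comparisons by camera with the preset correlation, the exception being liver at 6 h. With an estimated correlation, that call was kept in 1 comparison, heart at 1 h (adjusted p = 0.0159). Fatty acid oxidation genes and PPAR targets, a list that shares Pdk4 and Angptl4 with it, were higher in 11 of the 16 comparisons. That recurrence was kept in 0 comparisons with an estimated correlation. Tissues of the same rats enter several comparisons, so these counts are not of independent findings.

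**Figure D1:**
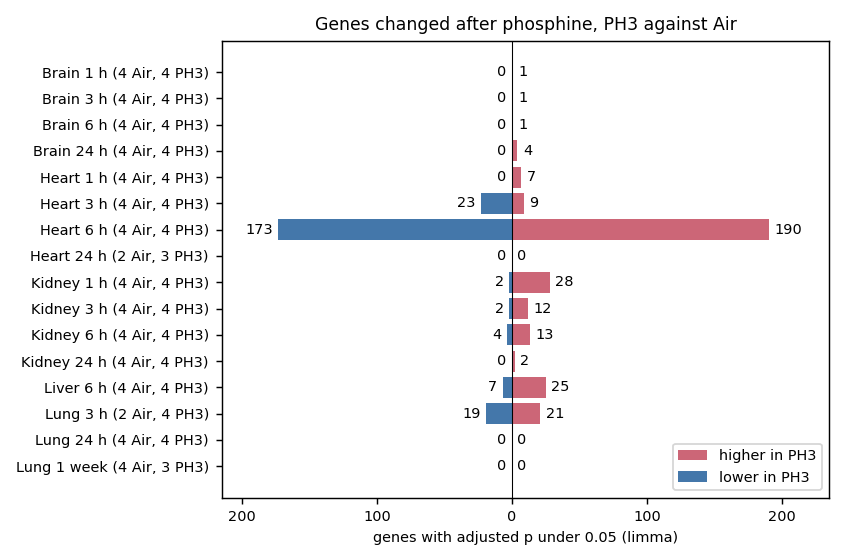
Number of genes with adjusted p under 0.05 in limma (horizontal axis) for each tissue and time (vertical axis), higher in PH3 to the right and lower to the left. Heart at 6 h has the longest bars, with 190 genes higher and 173 lower, and heart at 24 h and lung at 24 h and 1 week have 0.

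In brain at 1 h, Tmem252, a gene for a membrane protein, rose 2.54-fold, from 4.39 ± 0.17 to 5.74 ± 0.37 (n = 4 each). Its change of 1.34 ± 0.17 had an adjusted p of 0.00024, and all 4 PH3 arrays lay above all 4 Air arrays. Of the 26 glucocorticoid targets measured, 0 passed over all genes and 11 were higher adjusted over the list alone, among them Cdkn1a (1.00 ± 0.29), Sgk1 (0.85 ± 0.27), Nfkbia (0.82 ± 0.18) and Fkbp5 (0.79 ± 0.28). The list's median change was 0.39 (adjusted p = 2.06e-13 by camera), with adjusted p = 0.149 with an estimated correlation. Cholesterol synthesis genes were lower as a list (median -0.23, 1 of 19 passed adjusted over the list alone, Sqle), with adjusted p = 0.252 with an estimated correlation. Oligodendrocyte genes were lower too (median -0.18, Mog passed adjusted over the list alone), with adjusted p = 0.175 with an estimated correlation, and genes of T and natural killer cells were higher (median 0.11), with adjusted p = 0.425 with an estimated correlation. Hepatocyte genes and acute phase proteins were higher with medians of 0.88 and 0.35, at adjusted p = 0.889 and 0.872 with an estimated correlation. On PH3 rats 98 and 109 and Air rat 96 the hepatocyte genes stood 1.80, 2.10 and 1.38 above the median brain array. The 3' to 5' difference of beta-actin was 4.02 in PH3 and 3.51 in Air, and that of GAPDH 1.25 and 0.744 (exact p = 0.0857 and adjusted p = 0.457 for both). Tmem252 was the 1 gene that passed limma, 698 genes had an unadjusted p under 0.05, and 671.9 would be expected by chance. The next smallest p-values were those of Tnfrsf11b (-1.11 ± 0.24) and Phykpl (0.40 ± 0.08), both at adjusted p = 0.303. Tmem252 did not pass when the 8 arrays were fitted alone, and 1 other gene did. The count was 0 without the third of genes with the lowest signal, 2 with array weights, 2 without Air rat 163 and 4 without PH3 rat 98.

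Brain at 3 h showed a rise of Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, from 9.07 ± 0.31 to 10.30 ± 0.40 (n = 4 each). The change was 1.24 ± 0.21 (2.36-fold, adjusted p = 0.0295). Gpd1 is one of the 26 glucocorticoid targets, of which 1 rose over all genes and 7 did adjusted over the list alone, including Fkbp5, Cdkn1a and Mt2A. Their median change was 0.24 (adjusted p = 2.41e-18), with adjusted p = 0.0658 with an estimated correlation. Fibroblast genes were lower as a list (median -0.32, 0 of 12 passed), and so were extracellular matrix genes (median -0.21, 0 of 22 passed), with adjusted p = 0.518 and 0.619 with an estimated correlation. Besides Gpd1, no gene passed limma, and 542 had an unadjusted p under 0.05. Next came Frmd5 (-0.75 ± 0.15, adjusted p = 0.181) and Gpatch4 (1.07 ± 0.23, adjusted p = 0.234). The count was 0 when these 8 arrays were fitted alone and 4 with array weights. It was also 0 without any 1 of Air rats 97, 108 and 120 and PH3 rats 111, 122 and 152.

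At 6 h in brain, Mt2A, a metallothionein that binds zinc and copper, rose 2.82-fold, from 9.73 ± 0.41 to 11.23 ± 0.45 (n = 4 each). Its change was 1.49 ± 0.23 (adjusted p = 0.00505), and at 1 and 3 h it was 0.79 and 0.92 without passing. Of the 10 genes for metallothioneins and zinc transport, Mt2A rose over all genes, and Mt1 and Mt2A rose adjusted over the list alone. Mt1 was near the low end of the signal, at 4.04 ± 0.40 in PH3 and 3.48 ± 0.06 in Air. The 25th percentile of the array of Air rat 126 was 3.83. The list was higher (median 0.09, adjusted p = 0.000115) and stayed so with an estimated correlation (adjusted p = 0.0257). Interferon-stimulated genes were lower as a list (median -0.25), with Mx2 and Psmb8 passing adjusted over the list alone and adjusted p = 0.0585 with an estimated correlation. Glucocorticoid targets had a median of 0.21, at adjusted p = 0.245 with an estimated correlation. Hepatocyte genes had a median of 0.88, at adjusted p = 0.819 with an estimated correlation, and PH3 rat 141 stood 1.97 above the median brain array in them. Smooth muscle and pericyte genes had a median of -0.10, at adjusted p = 0.481 with an estimated correlation. Mt2A was the 1 gene that passed limma and 432 genes had an unadjusted p under 0.05, with Plin4 (1.05 ± 0.22) and Fibin (0.81 ± 0.17) next at adjusted p = 0.290. No gene passed when these arrays were fitted alone, or without Air rat 132, Air rat 138 or PH3 rat 141, and 2 did without PH3 rat 135.

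After 24 h, 4 genes were higher in PH3 brain, each at adjusted p = 0.0390. They were Hoxb5 (1.63 ± 0.31) and Hoxc4 (1.36 ± 0.26), which pattern the hindbrain and spinal cord, Ret (1.48 ± 0.27), a receptor of the GDNF family, and Tob2 (0.87 ± 0.15), an inhibitor of proliferation (n = 4 each). Of 11 cerebellum and brain stem markers, 1 rose over all genes (Hoxb5) and 9 did adjusted over the list alone, including Gabra6 (4.09 ± 1.14) and En2 (2.85 ± 0.75). Their median change was 1.63 (adjusted p = 1.71e-11), with adjusted p = 0.102 with an estimated correlation. Striatum markers were lower (median -0.76), with 0 of 11 passing over all genes and 10 adjusted over the list alone, including Drd1 (-1.60 ± 0.49) and Pdyn (-1.53 ± 0.40). Their adjusted p was 0.394 with an estimated correlation, and that of choroid plexus markers (median -0.36) was 0.758 with an estimated correlation. Oligodendrocyte genes had a median of 0.06, at adjusted p = 0.689 with an estimated correlation. The plot of regional markers shows that Air rats 89 and 145 stood apart from the other 30 brain arrays, with mean levels of 4.89 and 4.99 in the cerebellum and brain stem markers against 6.79 to 8.56. PH3 rat 91 had the highest of these values, 8.56, and the lowest mean of the striatum markers, 6.84, with 8.16 as the next lowest. Air rats 89 and 145 had the 2 highest striatum means, 9.38 and 9.54, with 9.06 as the next highest. Without these 2 arrays no gene passed limma, and 1639 genes had an unadjusted p under 0.05 with them. The count was 0 when the 8 arrays were fitted alone or without any 1 of Air rats 89 and 145 and PH3 rats 70 and 91. It was 2 without the third of genes with the lowest signal, 27 with array weights, 59 and 173 without Air rats 84 and 83, and 71 without PH3 rat 85. In hepatocyte genes Air rat 84 and PH3 rat 85 stood 3.20 and 3.42 above the median brain array.

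**Figure D2:**
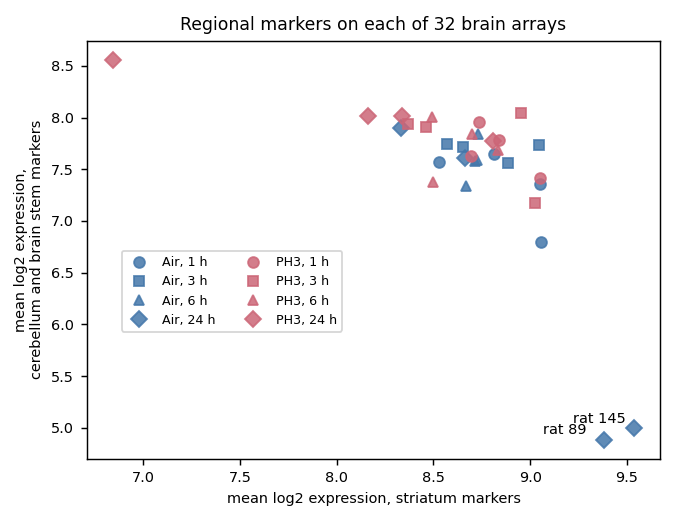
Mean log2 signal of 11 cerebellum and brain stem markers (vertical axis) against that of 11 striatum markers (horizontal axis) on each of the 32 brain arrays, with colour for exposure and shape for time. The Air arrays of rats 89 and 145 at 24 h lie at 4.89 and 4.99 on the vertical axis and the other 30 arrays between 6.79 and 8.56.

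In heart at 1 h, 7 genes rose and 0 fell. Fkbp5 rose 3.82-fold, from 6.65 ± 0.31 to 8.58 ± 0.31 (change 1.94 ± 0.25, n = 4 each, adjusted p = 0.000176). Pdk4, the kinase that shuts down pyruvate dehydrogenase, rose 2.40-fold, from 10.23 ± 0.17 to 11.49 ± 0.32 (adjusted p = 0.000176). The others were the transcription factors Cebpb (1.18 ± 0.22), Sox17 (0.94 ± 0.16) and Klf4 (0.63 ± 0.12), the regulator Id1 (0.55 ± 0.11) and the co-repressor Irf2bp2 (0.70 ± 0.13). All 4 PH3 arrays lay above all 4 Air arrays for each of these genes. Of 26 glucocorticoid targets, 3 rose over all genes (Fkbp5, Pdk4 and Cebpb) and 14 did adjusted over the list alone, including Fam107a (1.23 ± 0.39), Sult1a1 (1.22 ± 0.29) and Cdkn1a (1.04 ± 0.30). The list was higher with a median of 0.66 (adjusted p = 3.00e-19) and with an estimated correlation (adjusted p = 0.0159). Immediate early genes, with Klf4 as the 1 of 24 that rose, had a median of 0.25 and adjusted p = 0.674 with an estimated correlation. Hepatocyte genes had a median of 0.50 and adjusted p = 0.579 with an estimated correlation, and PH3 rat 116 stood 1.95 above the median heart array in them. Adipocyte genes (median 0.36, 0 of 11 passed) and endothelial genes (median 0.09, with Sox17 as the 1 of 16 that rose) were also higher as lists, at adjusted p = 0.821 and 0.579 with an estimated correlation. The PH3 arrays correlated less within their group than the Air arrays (0.981 against 0.988, permutation p = 0.0286, not exact for this measure, adjusted p = 0.343). The count was 2 without PH3 rat 98, PH3 rat 109, Air rat 163 or Air rat 168 and 3 without Air rat 96 or PH3 rat 116, and Fkbp5 and Pdk4 passed each time.

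At 3 h in heart, 9 genes rose and 23 fell. Pdk4 rose 2.26-fold (1.18 ± 0.16, adjusted p = 0.00131) and Fkbp5 2.64-fold (1.40 ± 0.25), and the largest rise was that of the nucleolar protein Nom1 (1.79 ± 0.37, 3.45-fold). The transcription factor gene Mycn fell by 1.46 ± 0.30, the growth factor Fgf9 by 1.40 ± 0.24, and cyclin D1 (Ccnd1) by 0.85 ± 0.14 (adjusted p = 0.00389). Dhcr7, the last enzyme of cholesterol synthesis, fell by 1.28 ± 0.28, and Srebf2, the transcription factor that drives that pathway, by 0.66 ± 0.12 (n = 4 each). Of 19 cholesterol synthesis genes, these 2 fell over all genes and 5 did adjusted over the list alone, the others being Idi1, Cyp51 and Msmo1. The list was lower (median -0.25, adjusted p = 0.00225), with adjusted p = 0.546 with an estimated correlation. Of 26 glucocorticoid targets, 2 rose over all genes and 9 adjusted over the list alone (median 0.31), with adjusted p = 0.101 with an estimated correlation. Sesn1 (0.77 ± 0.13), a p53 target, and Herpud1 (0.55 ± 0.10), which serves protein degradation at the endoplasmic reticulum, rose too. Fibroblast genes were lower as a list (median -0.18, 0 of 12 passed) and adrenal gland genes higher (median 0.28, 0 of 9 passed), at adjusted p = 0.622 and 0.102 with an estimated correlation. Id2 (-1.03 ± 0.22), an inhibitor of differentiation, and Irf1 (-0.54 ± 0.12) fell. The natriuretic peptide gene Nppb (-0.69 ± 0.17, adjusted p = 0.0606) and Per1 (0.98 ± 0.23, adjusted p = 0.0596) did not pass. The other probe set of Srebf2 gave 0.14, and the count was 14 when the 8 arrays were fitted alone and 49 with all probe sets. It was 6 without PH3 rat 122, 17 without Air rat 108 and 85 without PH3 rat 105. Of the 32 genes, 6 passed without any 1 array, Ccnd1, Fam167a, Fgf9, Pdk4, Rhobtb1 and Sema6d. The other genes named here that had passed, Mycn and Fkbp5 among them, each lost their call in at least 1 such fit.

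Heart at 6 h had 190 genes higher and 173 lower. The monocyte chemokine Ccl2 rose 10.0-fold, from 6.52 ± 0.24 to 9.85 ± 1.27 (change 3.33 ± 0.40, n = 4 each, adjusted p = 1.19e-05), and Ccl7 rose 7.10-fold (2.83 ± 0.47). The muscle genes Klhl40, which stabilises thin filaments, and Ankrd2, which responds to stretch, rose 8.02-fold and 7.25-fold. Mt2A rose 6.38-fold, the neuropeptide galanin (Gal) 6.78-fold, the lipoprotein lipase inhibitor Angptl4 5.55-fold and the hydrolase Abhd2 5.71-fold. Without PH3 rat 141, whose array stood apart, the changes were 2.32 for Klhl40, 2.21 for Ccl7, 2.03 for Mt2A, 1.80 for Gal, 1.75 for Angptl4 and 1.59 for Timp1, each over 1.5 times smaller in fold. Pdk4 rose for the third time (1.63 ± 0.16, 3.09-fold), and the potassium channel subunit Kcne1 (1.91 ± 0.24), the small heat shock protein Hspb1 (1.10 ± 0.12) and the light chain Myl1 (1.99 ± 0.34) rose as well. Of 21 genes for cardiac stress and remodelling, 8 rose over all genes and 13 adjusted over the list alone, with 0 falling. They included the matrix inhibitor Timp1 (2.21 ± 0.35), Tnfrsf12a (2.24 ± 0.39), the calcineurin regulator Rcan1 (1.00 ± 0.17) and Nppb (0.72 ± 0.17). The list's median was 0.62 (adjusted p = 7.30e-14), with adjusted p = 0.0658 with an estimated correlation.

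In the same hearts, 5 of 29 inflammatory genes rose over all genes (Il1b, Ccl2, Ccl7, Sele and Nfkbiz) and 9 adjusted over the list alone. Their median was 0.61 (adjusted p = 4.18e-09), with adjusted p = 0.277 with an estimated correlation. Ccl2 and Ccl7 passed without any 1 array, while Il1b, Sele and Nfkbiz each lost their call in at least 1 such fit. Without PH3 rat 141 the change was 1.03 for Sele, against 1.72 with it, and 0.76 for Nfkbiz, against 1.34. Immediate early genes had the same median of 0.61, with 3 of 24 rising over all genes (Egr2, Nr4a3 and Maff), 8 adjusted over the list alone, and adjusted p = 0.468 with an estimated correlation. None of these 3 passed in every fit without 1 array. Without PH3 rat 141 their changes were 1.34, 1.09 and 0.50, against 1.92, 1.39 and 1.09 with it. Of 13 neutrophil genes 1 rose, lysozyme Lyz2 (0.36 ± 0.09), which macrophages also express, and the complement gene C1qb (0.56 ± 0.15) rose beside it. The neutrophil list had adjusted p = 0.245 with an estimated correlation. Endothelial genes (median 0.17, 0 of 16 passed), adipocyte genes (median 0.33, 0 of 11 passed) and extracellular matrix genes (median 0.15, with Timp1 and Adamts1 rising of 22) were higher as lists, at adjusted p = 0.523, 0.819 and 0.689 with an estimated correlation. Interferon-stimulated genes were lower, with 3 of 23 falling over all genes, Usp18 (-1.04 ± 0.17), Psmb9 (-0.57 ± 0.15) and Bst2 (-0.53 ± 0.13), and 11 adjusted over the list alone. Their median was -0.38 (adjusted p = 2.18e-07), with adjusted p = 0.352 with an estimated correlation. Klhl38 (-1.76 ± 0.33), Rasd2 (-1.40 ± 0.24) and Hs3st5 (-1.40 ± 0.38) fell, and so did Ddit4l (-1.35 ± 0.34), an inhibitor of mTOR signalling, whose change was -0.66 without PH3 rat 141. Hmox1 (1.40 ± 0.45, adjusted p = 0.0946), Cdkn1a (0.99 ± 0.30, adjusted p = 0.0685) and the glutathione synthesis gene Gclc (0.75 ± 0.22, adjusted p = 0.0617) did not pass. The 23 genes of cytochrome c oxidase and its assembly had a median of -0.04 (adjusted p = 0.315 by camera). The count was 54 when the 8 arrays were fitted alone and 751 with array weights, and other probe sets gave -0.26 for Nfkbiz and 0.15 for Mtf1, which had fallen by 0.47 ± 0.09. The count was 134 without PH3 rat 141, 604 without PH3 rat 128, and 204, 204, 166 and 195 without Air rats 126, 132, 138 and 156.

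**Figure D3:**
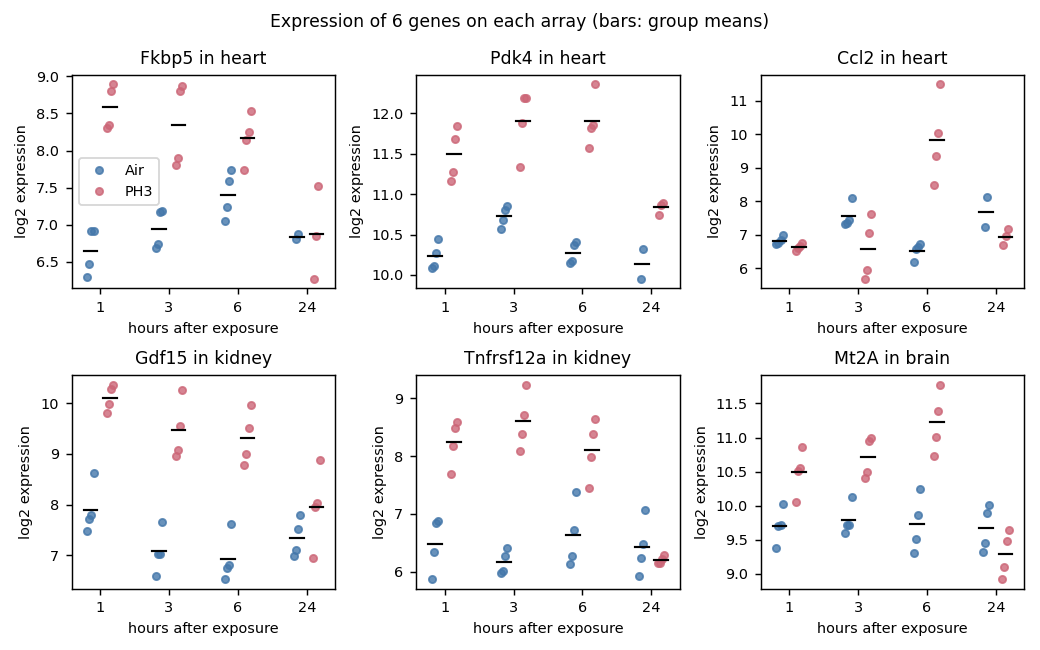
Log2 signal (vertical axes) of 6 genes on each array at 1, 3, 6 and 24 h after exposure (horizontal axes, ordered but not to scale), with Air in blue, PH3 in red and bars at the group means. Fkbp5 in heart at 1 h has means of 8.58 in PH3 and 6.65 in Air, and Ccl2 in heart at 6 h has means of 9.85 and 6.52.

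After 24 h no gene in heart passed limma, with 2 Air and 3 PH3 arrays, and 405 genes had an unadjusted p under 0.05. The smallest p-values were those of Gins1 (-0.92 ± 0.17, adjusted p = 0.164), which serves DNA replication, the clock gene Per2 (1.17 ± 0.26, adjusted p = 0.474) and C1ql3 (-0.87 ± 0.19, adjusted p = 0.474). Proliferation genes were lower as a list, with a median of -0.74, 0 of 28 passing over all genes and 1 adjusted over the list alone, Mcm5 (-0.99 ± 0.26). That call (adjusted p = 2.88e-14) had adjusted p = 0.352 with an estimated correlation. Glucocorticoid targets had a median of 0.28 with Per1, Pdk4, Ddit4 and Nfkbia higher adjusted over the list alone, and adjusted p = 0.187 with an estimated correlation. Clock genes and glucocorticoid targets vary with the hour of day, which is not known here for PH3 and Air rats. Other probe sets gave -0.06 for Per2 and 0.28 for C1ql3. The count was 2 when these arrays were fitted alone, 2 with array weights, 1 with all probe sets and 1 without Air rat 84, whose hepatocyte genes stood 1.47 above the median heart array. The hepatocyte list was lower in PH3 (median -0.41), at adjusted p = 0.819 with an estimated correlation.

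In kidney at 1 h, 28 genes rose and 2 fell. The largest rises were those of Atf3 (2.52 ± 0.41, 5.75-fold) and Fosb (2.52 ± 0.38, 5.72-fold), both early transcription factors. Gdf15, a secreted stress cytokine, rose 4.64-fold, from 7.90 ± 0.50 to 10.11 ± 0.26 (n = 4 each, adjusted p = 0.00117). Ddit3 (1.49 ± 0.18, adjusted p = 9.40e-05) and Atf4 (0.63 ± 0.11), transcription factors of the integrated stress response, rose with it. So did Tnfrsf12a (1.75 ± 0.29), the coagulation initiator F3, also called tissue factor (1.57 ± 0.21), Maff (1.65 ± 0.36) and Nr4a3 (1.60 ± 0.22). Of 29 genes of the unfolded protein and integrated stress response, 4 rose over all genes (Atf3, Atf4, Ddit3 and Gdf15) and 6 adjusted over the list alone. The list was higher (median 0.27, adjusted p = 7.06e-10), also with an estimated correlation (adjusted p = 0.0159). Of 24 immediate early genes 5 rose, with adjusted p = 0.558 with an estimated correlation, and of 24 kidney injury genes 2 rose, Atf3 and Gdf15, with adjusted p = 0.758 with an estimated correlation. The injury markers Havcr1 (0.24 ± 0.74) and Lcn2 (-0.17 ± 0.57) did not pass. Ppp1r10 (-1.01 ± 0.20) and Zmynd8 (-0.57 ± 0.12) fell, and Fkbp5 did not pass (1.19 ± 0.30, adjusted p = 0.118). The 3' to 5' difference of beta-actin was 2.94 in Air rat 96 and 2.97 and 3.06 in PH3 rats 109 and 116, against 3.27 to 3.76 in the other 5 kidneys. Fitted alone, the 8 arrays gave 1 gene, and array weights gave 113. Without Air rat 168 or PH3 rat 109 the count was 18, and 15 of the 30 genes passed without any 1 array.

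Kidney at 3 h had 12 genes higher and 2 lower. Tnfrsf12a rose 5.41-fold, from 6.17 ± 0.21 to 8.61 ± 0.49 (n = 4 each, adjusted p = 6.63e-05). Gdf15 rose 5.25-fold (2.39 ± 0.34), and Ddit3 (1.17 ± 0.18) and Atf4 (0.60 ± 0.11) rose again. The hormone gene Sct, for secretin (1.43 ± 0.22), Fkbp5 (1.58 ± 0.30), Tmem252 (1.38 ± 0.25) and Depp1 (1.31 ± 0.25), a FOXO target, rose too. The genes that fell were Ppp2r2b (-1.17 ± 0.24), a phosphatase subunit, and A4galt (-1.11 ± 0.22). The unfolded protein and integrated stress response list was higher (median 0.23, adjusted p = 2.13e-07), with 3 of 29 members rising over all genes and 9 adjusted over the list alone, and stayed higher with an estimated correlation (adjusted p = 0.0323). Of 26 glucocorticoid targets, 3 rose over all genes (Fkbp5, Errfi1 and Nfkbia), while 11 rose and 1 fell adjusted over the list alone, with adjusted p = 0.102 with an estimated correlation. The 8 genes that rose at both 1 and 3 h were Atf4, Ddit3, Errfi1, Gdf15, Maff, Tacc2, Tmem252 and Tnfrsf12a, against 0.025 expected from independent lists. Both lists came from the same fit, with a shared estimate of the spread of each gene, so they are not independent. Hepatocyte genes and acute phase proteins had medians of 1.00 and 0.68, with adjusted p = 0.758 and 0.819 with an estimated correlation, and PH3 rat 152 stood 4.06 above the median kidney array in hepatocyte genes. Genes of the distal nephron and collecting duct were lower as a list (median -0.25, 0 of 17 passed), at adjusted p = 0.538 with an estimated correlation. Within-group correlations were lower in PH3 than in Air (0.972 against 0.987, permutation p = 0.0286, not exact for this measure, adjusted p = 0.343). The count was 2 when the 8 arrays were fitted alone and 51 without PH3 rat 105. It was 9, 5 and 7 without Air rats 97, 120 and 150, and 5 without PH3 rat 122 or PH3 rat 152.

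At 6 h in kidney, Gdf15 still stood 5.24-fold higher (9.31 ± 0.53 against 6.92 ± 0.48, n = 4 each, adjusted p = 0.00185), in a set of 13 genes higher and 4 lower. Tnfrsf12a (1.48 ± 0.29) and Atf4 (0.54 ± 0.11) also rose. New among the genes higher were the mitochondrial carrier Slc25a25 (1.74 ± 0.33), the tight junction gene Cldn22 (1.60 ± 0.29) and the glucose transporter Slc2a2 (1.09 ± 0.21). Of 18 NRF2 targets, genes of the defence against oxidants, 1 rose over all genes, the autophagy receptor Sqstm1 (0.61 ± 0.12), and 7 did adjusted over the list alone, including Srxn1 (1.75 ± 0.38), Hmox1 (0.79 ± 0.30) and Txnrd1 (0.43 ± 0.10). The list was higher (median 0.32, adjusted p = 3.15e-07), also with an estimated correlation (adjusted p = 0.0257). Interferon-stimulated genes were lower (median -0.49, adjusted p = 3.19e-12), with 0 of 23 falling over all genes and 9 adjusted over the list alone, including Mx1 (-1.49 ± 0.45), and adjusted p = 0.102 with an estimated correlation. Aif1, a macrophage gene, fell by 1.02 ± 0.20, and of the 19 genes of macrophages and microglia 3 fell adjusted over the list alone (Aif1, C1qa and Adgre1), with adjusted p = 0.464 with an estimated correlation. Genes of T and natural killer cells (median -0.25), fibroblasts (median -0.24) and extracellular matrix (median -0.22) were lower as lists too, with 0 members passing and adjusted p = 0.778, 0.518 and 0.758 with an estimated correlation. Ddit3 did not pass at this time (0.71 ± 0.18, adjusted p = 0.129). No gene passed when the 8 arrays were fitted alone and 103 did with array weights, and other probe sets gave -0.07 for Sqstm1 and 0.25 for Aif1. The count was 1, 6 and 2 without Air rats 132, 138 and 156 and 11, 9 and 1 without PH3 rats 128, 134 and 141, with Gdf15 passing each time.

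After 24 h, 2 genes were higher in PH3 kidney, Depp1 (1.62 ± 0.25, 3.08-fold, adjusted p = 0.00415) and Errfi1 (0.95 ± 0.13, 1.94-fold, adjusted p = 0.00129). Both passed without any 1 array (n = 4 each), and the next smallest p was that of Per1 (1.38 ± 0.29, adjusted p = 0.206). Proliferation genes were higher as a list (median 0.41, adjusted p = 2.03e-16), with 0 of 28 passing over all genes and 3 adjusted over the list alone, Cdk1 (0.66 ± 0.20), Nusap1 (0.64 ± 0.21) and Rrm2 (0.62 ± 0.20). That call held with an estimated correlation (adjusted p = 0.0232). Fibroblast genes (median -0.29) and extracellular matrix genes (median -0.17) were lower as lists, with 0 members passing over all genes and adjusted p = 0.415 and 0.819 with an estimated correlation. Of 18 clock genes, 5 were higher adjusted over the list alone (Per1, Per2, Per3, Dbp and Usp2) and 3 lower (Bmal1, Cry1 and Npas2), with adjusted p = 0.0585 with an estimated correlation. Glucocorticoid targets, a list that holds Errfi1, had a median of 0.24 and adjusted p = 0.0585 with an estimated correlation. The hour of sampling of PH3 and Air rats is not known for these kidneys either, so clock and glucocorticoid changes cannot be tied to exposure alone. The count of 2 beside 318 genes with an unadjusted p under 0.05 became 4 with array weights.

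Liver at 6 h had 25 genes higher and 7 lower. Cyp4a8, a fatty acid hydroxylase, rose from 5.30 ± 0.94 to 7.79 ± 0.47 (2.49 ± 0.39, n = 4 each, adjusted p = 0.0323). Got1, the cytosolic aspartate aminotransferase (1.59 ± 0.26), and Agxt, the alanine-glyoxylate aminotransferase (1.26 ± 0.13, adjusted p = 0.00420), rose with it. Also higher were Cox10 (1.18 ± 0.19), which serves the haem synthesis for cytochrome c oxidase, the mitochondrial import channel Tomm40 (1.03 ± 0.19), the mitochondrial RNA polymerase Polrmt (0.88 ± 0.16) and Cpt2 (0.65 ± 0.11). Of 45 genes for respiratory complexes I, II, III and ATP synthase, 0 passed over all genes and 8 rose adjusted over the list alone, including Atp5mc1 (0.37 ± 0.10) and Cyc1 (0.28 ± 0.06). Their median was 0.12 (adjusted p = 4.38e-08), with adjusted p = 0.427 with an estimated correlation. For cytochrome c oxidase and its assembly, 1 of 23 rose over all genes, and 4 rose and 1 fell adjusted over the list alone, with adjusted p = 0.574 with an estimated correlation. Among 32 genes of fatty acid oxidation and PPAR targets, 1 rose over all genes and 9 adjusted over the list alone, including Plin5 (1.41 ± 0.35) and Cpt1a (0.65 ± 0.13), with adjusted p = 0.758 with an estimated correlation. The mitochondrial biogenesis list (1 of 23 rose, 4 adjusted over the list alone) had adjusted p = 0.382 with an estimated correlation.

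Among the liver genes that fell were Shank2 (-1.32 ± 0.21), the interferon-induced GTPase Gbp7 (-0.98 ± 0.13), Rarres1 (-0.90 ± 0.10, adjusted p = 0.00638) and the bile acid importer Slc10a1 (-0.47 ± 0.08). Interferon-stimulated genes were lower as a list in liver too (median -0.43, adjusted p = 1.42e-06), with 4 of 23 falling adjusted over the list alone (Mx1, Mx2, Irf7 and Gbp2) and adjusted p = 0.579 with an estimated correlation. Macrophage and microglia genes were lower beside them (median -0.22, adjusted p = 0.00108), with 0 of 19 falling over all genes, Aif1 adjusted over the list alone, and adjusted p = 0.613 with an estimated correlation. Cholesterol synthesis genes had a median of -0.41, with Idi1 and Cyp51 falling adjusted over the list alone and adjusted p = 0.758 with an estimated correlation. Of 18 NRF2 targets 1 rose and 4 fell adjusted over the list alone, with adjusted p = 0.238 with an estimated correlation, and Gclc was -0.65 ± 0.14 (adjusted p = 0.0640). Correlations within the group were 0.986 in PH3 and 0.989 in Air (permutation p = 0.0286, not exact for this measure, adjusted p = 0.343). Fitted alone, the 8 arrays gave 161 genes, array weights gave 91, and the other probe set of Shank2 gave 0.23. The count was 14, 2, 9 and 2 without Air rats 126, 132, 138 and 156 and 2, 6, 64 and 3 without PH3 rats 128, 134, 140 and 141, with Agxt and Rarres1 passing each time.

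In lung at 3 h, 21 genes rose and 19 fell, with 4 PH3 and 2 Air arrays. Depp1 rose 6.86-fold, from 7.35 ± 0.29 to 10.12 ± 0.39 (2.78 ± 0.50, adjusted p = 0.0172), and Fkbp5 6.29-fold, from 6.93 ± 0.20 to 9.58 ± 0.53 (2.65 ± 0.36, adjusted p = 0.00220). Galanin (2.06 ± 0.32), the haemoglobin scavenger receptor Cd163 (2.02 ± 0.34), Map3k6 (1.85 ± 0.31) and the cannabinoid receptor Cnr1 (1.83 ± 0.33) rose as well. Of 26 glucocorticoid targets, 4 rose over all genes (Fkbp5, Nfkbia, Klf9 and Errfi1) and 11 adjusted over the list alone. Their median was 0.90 (adjusted p = 2.23e-16), with adjusted p = 0.102 with an estimated correlation. Pdk4 (2.97 ± 0.68, adjusted p = 0.0655) and Mt2A (2.60 ± 0.61, adjusted p = 0.0710) did not pass. G0s2, an inhibitor of fat breakdown, was 4.72-fold lower (-2.24 ± 0.31), and Ooep (-2.22 ± 0.43), Tmem119 (-2.16 ± 0.35) and the adenosine receptor Adora2a (-1.47 ± 0.30) fell. Fatty acid oxidation genes had a median of 0.20, with Acot1 (1.63 ± 0.32) as the 1 of 32 that rose and adjusted p = 0.415 with an estimated correlation. The 4 genes higher in both lung and kidney at 3 h were Depp1, Errfi1, Fkbp5 and Nfkbia. The 2 comparisons share Air rat 150 and PH3 rat 152, so their lists are not independent.

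The same lung arrays differed in markers of other tissues. Skeletal muscle genes had a median of 1.44, with 0 of 10 passing and adjusted p = 0.574 with an estimated correlation, and PH3 rats 147 and 148 stood 3.26 and 3.43 above the median lung array in them. Adipocyte genes had a median of 0.93 (0 of 11 passed), with adjusted p = 0.819 with an estimated correlation. Hepatocyte genes had a median of -0.83, with adjusted p = 0.816 with an estimated correlation, and Air rat 144 stood 1.99 above the median lung array in them. Genes of T and natural killer cells had a median of -0.45, with adjusted p = 0.879 with an estimated correlation. Without the arrays of rats 147 and 148, an alternative chosen after seeing the data, 1 gene passed. The count was 520 when the 6 arrays were fitted alone and 2561 with array weights, and the other probe set of Dact3, which had fallen by 1.42 ± 0.29, gave 0.04. It was 2 without Air rat 144, 13, 16 and 72 without PH3 rats 147, 148 and 152, and the gene that passed without any 1 array was Atp1b1.

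Later in lung, no gene passed limma at 24 h (190 with an unadjusted p under 0.05) or at 1 week (285). At 24 h the smallest p-values were those of Bcl2l14 (0.75 ± 0.19), the haem synthesis gene Alas1 (0.73 ± 0.19) and Rprml (1.82 ± 0.49, n = 4 each). Proliferation genes were lower (median -0.41, adjusted p = 4.63e-17), with 0 of 28 passing and adjusted p = 0.102 with an estimated correlation. Clock genes were higher, with 5 of 18 passing adjusted over the list alone (Per2, Nr1d1, Nr1d2, Dbp and Tef) and adjusted p = 0.109 with an estimated correlation. Skeletal muscle genes had a median of 0.77 and adjusted p = 0.674 with an estimated correlation, and PH3 rat 155 stood 3.00 above the median lung array in them. Smooth muscle, erythroid and B cell genes were higher as lists at 24 h (medians 0.27, 0.16 and 0.04, 0 members passed), with adjusted p = 0.427, 0.780 and 0.515 with an estimated correlation. Correlations within the group at 24 h were 0.986 in PH3 and 0.973 in Air (permutation p = 0.0286, not exact for this measure, adjusted p = 0.343). At 1 week, with 4 Air and 3 PH3 arrays, Tent5b (1.95 ± 0.41), Atp1b1 (0.55 ± 0.13) and Dmrt1 (0.34 ± 0.08) had the smallest p-values. Of 18 clock genes, 8 were higher and 3 lower adjusted over the list alone, among them Dbp (2.67 ± 0.66) and Bmal1 (-1.64 ± 0.42), with adjusted p = 0.269 with an estimated correlation. The PH3 and Air arrays overlapped in both genes, and the Air arrays varied widely. Dbp was 9.75 ± 0.18 in PH3 and 7.08 ± 2.02 in Air, and Bmal1 4.39 ± 0.13 and 6.03 ± 1.22. Air rat 133 lay near the PH3 level in Bmal1, at 4.20 against 6.52 to 6.83 on the other Air arrays. Smooth muscle genes were lower (median -0.23) and airway epithelium genes higher (median 0.14) as lists, with 0 members passing and adjusted p = 0.537 and 0.579 with an estimated correlation. Glucocorticoid targets had medians of 0.27 at 24 h and 0.37 at 1 week, with adjusted p = 0.427 and 0.378 with an estimated correlation. The hour of day at which PH3 and Air rats were sampled is not known here, and clock genes and glucocorticoid targets vary with it. The count at 1 week was 14 without Air rat 133.

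**Figure D4:**
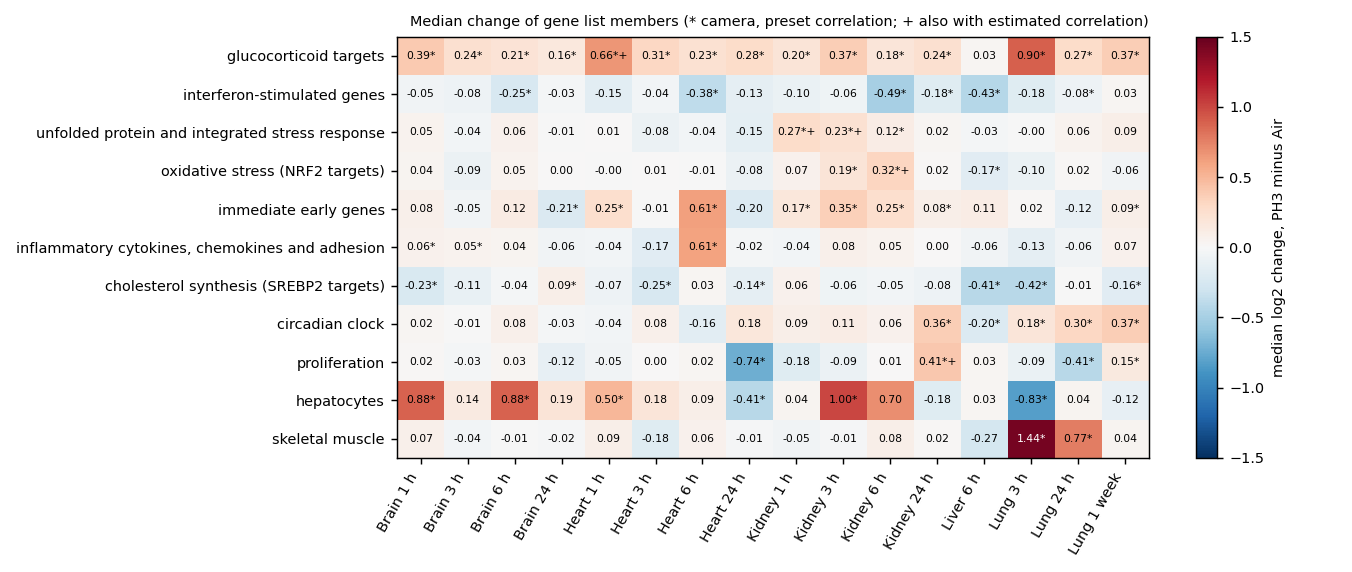
Median log2 change, PH3 minus Air, of the members of 11 gene lists (vertical axis) in each of the 16 comparisons (horizontal axis), with red for higher and blue for lower. Glucocorticoid targets are marked as higher in 15 comparisons and interferon-stimulated genes as lower in 6, with a star for a camera call at the preset correlation and a plus where it held with an estimated correlation.

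Times within a tissue were compared by an F test on the exposure effects. In heart 36 genes differed between times, among them Abhd2, Ccl2 and Hspb1, each at adjusted p = 0.000377. At 1, 3, 6 and 24 h the effects on Nppb were 0.20, -0.69, 0.72 and -0.09 (adjusted p = 0.0175), those on Nom1 -0.31, 1.79, -0.72 and -1.27 (adjusted p = 0.0205), and those on Myl1 1.41, -0.42, 1.99 and -0.67 (adjusted p = 0.0117). In brain, kidney and lung limma found 0 genes that differed, with 571, 666 and 433 at an unadjusted p under 0.05 and smallest adjusted p of 0.210, 0.0770 and 0.567. The heart count was 134 with array weights, 65 without PH3 rat 128 and 23 without Air rat 138, both at 6 h. Array weights gave 11 genes in kidney and 87 in lung, and all probe sets gave 2 in kidney.

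Brain, heart and kidney were compared in the same way. Gdf15 rose in kidney and not in the other 2 tissues, with effects of 0.24, 0.31 and 2.22 in brain, heart and kidney at 1 h (adjusted p = 0.00151), 0.10, 0.03 and 2.39 at 3 h, and 0.21, 0.20 and 2.39 at 6 h. Ddit3 and Atf4 differed at 1 and 3 h, with effects of 1.49 and 0.63 in kidney at 1 h. The effects on Gnb3 at 1 h were 1.67, -0.44 and -0.10, and those on Miox 1.63, 0.71 and 0.04. Tnfrsf12a at 3 h had effects of -0.03, -0.39 and 2.44 (adjusted p = 0.000577), and Fgf9 of 0.02, -1.40 and 0.10 (adjusted p = 0.00167). At 6 h the muscle gene Myl1 had effects of 0.01, 1.99 and 0.01 (adjusted p = 1.65e-05), Ccl2 of 0.02, 3.33 and -0.39, and Slc25a25 of 0.19, 0.02 and 1.74. In all, 7 genes differed between tissues at 1 h, 18 at 3 h and 41 at 6 h. With the rat as a block the counts were 5, 4 and 33, of which 4, 4 and 25 were shared with the fits without a block. Of the genes named here, Atf4 at 1 and 3 h (adjusted p = 0.0506 and 0.0548) and Ccl2 at 6 h (adjusted p = 0.0580) no longer passed with the block. Array weights gave 432 genes at 1 h and 164 at 6 h, and 9 genes differed at 3 h without the third of genes with the lowest signal. Leaving out each rat in turn gave 1 to 26 genes at 1 h, 6 to 50 at 3 h and 5 to 60 at 6 h.

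Over all comparisons, camera with the preset correlation called 136 of 692 list tests, 94 higher and 42 lower, of which 6 held with an estimated correlation. These 6 were glucocorticoid targets in heart at 1 h, the unfolded protein and integrated stress response in kidney at 1 and 3 h, NRF2 targets in kidney at 6 h, metallothioneins and zinc transport in brain at 6 h, and proliferation in kidney at 24 h. Fry, which asks whether the members changed at all, called 10 of the 692. Hepatocyte genes were called in 6 comparisons, 4 higher and 2 lower, and the plot of hepatocyte markers shows 12 of the 114 arrays outside the liver that stood more than 1 above the median of their tissue.

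**Figure D5:**
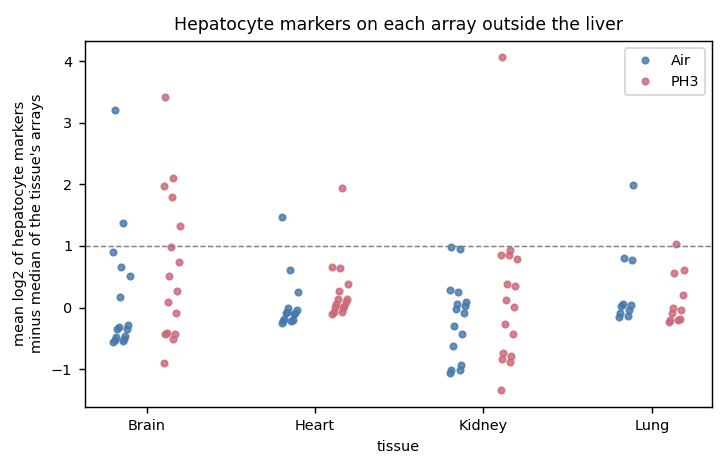
Mean log2 signal of the hepatocyte markers on each of 114 arrays, minus the median of the tissue's arrays (vertical axis), for brain, heart, kidney and lung (horizontal axis), with Air in blue and PH3 in red. The dashed line is at 1, and 4 Air and 8 PH3 arrays lie above it, the highest being a kidney array of PH3 rat 152 at 4.06.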

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

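The regional markers of brain at 24 h, the hepatocyte genes on single arrays and the muscle genes of heart at 6 h were chosen for weighing after they were seen. The tests of exposure for the first 2, and both tests for the muscle genes, were written only after the result was known. The tests of brain part and of carried-over liver RNA were written before they were run, and the splits of the samples were planned before the data were examined.

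Cerebellum and brain stem markers were higher and striatum markers lower in PH3 brain at 24 h, which could come from a different part of the brain on the Air arrays of rats 89 and 145 or from exposure. On 20 further regional markers, these 2 arrays lay 0.69 below the lowest of the other 30 brain arrays, at 5.30 and 5.33 against 6.02, and in the striatum markers they were the 2 highest, at 9.38 and 9.54 against 9.06 for the next. PH3 minus Air was 1.74 in the fixed cerebellum and brain stem markers and -0.94 in the striatum markers, and without these 2 arrays it was 0.33 and -0.46. Without PH3 rat 91, the lowest array in the striatum markers, the striatum difference was -0.54. Without rats 89, 91 and 145 together it was -0.06, so these arrays carry nearly all of the striatum difference. The lowest PH3 array minus the highest Air array was -0.13 in the fixed markers, within the SD of 0.33 of the PH3 arrays, so that test did not decide on exposure. Rats 89 and 145 were not exposed, and lay at 4.89 and 4.99 in the fixed markers. The other Air arrays at 24 h lay at 7.61 and 7.90. These levels argue against exposure for the part of the cerebellum and brain stem difference that rats 89 and 145 carry. For what remained without them, and for the striatum markers, exposure stays open. A different dissection of the brains of rats 89 and 145 could account for the part of both differences that they carry, as a hypothesis found and tested on the same data.

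Hepatocyte genes stood more than 1 above the median of their tissue on 12 single arrays outside the liver. This could come from RNA carried over from liver or from a response to exposure. Over 155 further liver genes, the excess on these arrays followed the level in liver with a median rho of 0.67, against -0.04 on the other arrays, and albumin (Alb) was 13.6 in kidney of PH3 rat 152 against a tissue median of 9.51. The tissue medians of albumin were themselves uneven, at 9.80 in brain and 9.51 in kidney against 5.33 in heart and 5.54 in lung. The count of 12 therefore does not show that the other arrays were free of liver transcripts. Of the 12 arrays 4 were from Air rats, so exposure alone does not account for these 12. Liver RNA in these samples is therefore likely, and the hepatocyte and acute phase list calls outside the liver may reflect it.

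The muscle genes Myl1, Klhl40 and Ankrd2 rose in heart at 6 h, which could come from skeletal muscle RNA, from rat 141 alone or from the heart itself. The other 9 skeletal muscle genes changed by a median of 0.0591, which speaks against skeletal muscle RNA. Without rat 141 the changes were 1.95 for Myl1, 2.32 for Klhl40 and 2.37 for Ankrd2, against 1.99, 3.00 and 2.86 with it, so this array adds to 2 of the changes and does not carry the result alone. A response of the heart itself stays open as a hypothesis.

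The following values stood apart in their groups. In 463 sets of at least 4 arrays, 39 arrays stood apart, or 8.42%. By the design of the rule, chance alone marks about 1 in 20 sets. Heart of PH3 rat 141 at 6 h did so 10 times. Its median correlation with its group was 0.975 against 0.990 to 0.991, and its levels were 10.01 for Abhd2, 13.09 for Hspb1, 10.76 for Tnfrsf12a, 11.04 for Mcl1, 6.57 for Plekhf1, 6.56 for Pik3ip1, 5.65 for Ddit4l, 11.64 for Xirp1 and 8.18 for Gclc.

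The 3' to 5' difference of beta-actin was 2.94 in kidney of Air rat 96 at 1 h and 2.81 in lung of PH3 rat 154 at 3 h, and that of GAPDH was 1.75 in brain of PH3 rat 105 at 3 h. Median correlations that stood apart in brain were 0.969 for Air rat 145 at 24 h, 0.982 for Air rat 97 at 3 h and 0.987 for PH3 rat 105 at 3 h. Elsewhere they were 0.953 for lung of Air rat 84 at 24 h, 0.980 for heart and 0.978 for kidney of Air rat 108 at 3 h, and 0.984 for liver of PH3 rat 141 at 6 h.

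In brain, Phykpl was 3.47 in Air rat 163 at 1 h, and Fkbp5 was 6.64 in Air rat 108 at 3 h and 8.87 in PH3 rat 141 at 6 h. In heart, Cebpb was 9.38 in PH3 rat 115 at 1 h. At 3 h in heart, Mycn was 6.22 in Air rat 108, Fmo2 7.07 in Air rat 150, Id2 8.03 in PH3 rat 152, Irf1 8.49 in PH3 rat 105 and Per1 7.36 in PH3 rat 111. At 6 h in heart, Nr4a3 was 5.49 in Air rat 156 and Ddit4l 8.98 in Air rat 126.

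At 3 h in kidney, Sct was 6.03 in PH3 rat 122, Atf4 10.18 in Air rat 150 and A4galt 6.57 in PH3 rat 111, and Atf4 was 10.76 in PH3 rat 140 at 6 h. In lung, Fkbp5 was 10.37 and Depp1 10.70 in PH3 rat 147 at 3 h, Per1 was 8.34 in Air rat 84 at 24 h, and Bmal1 was 4.20 in Air rat 133 at 1 week against 6.52 to 6.83.

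Exposure effects differed between times for 36 genes in heart, and between brain, heart and kidney for 7 genes at 1 h, 18 at 3 h and 41 at 6 h. Of the 12071 probe sets without 1 gene name, 1 changed in brain at 24 h, 28 in heart at 3 h, 142 in heart at 6 h, 10 in kidney at 1 h, 4 in kidney at 3 h, 13 in kidney at 6 h, 6 in liver at 6 h and 49 in lung at 3 h.

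Each comparison was set against the splits of its own arrays, 35 with the real one included. In brain, 3 splits were as large as the real one at 1 h (1 gene, highest other 22), 2 at 3 h (1, highest other 1), 1 at 6 h (1, highest other 0) and 4 at 24 h (4, highest other 2683). By this count the real split stood alone at 6 h only, where a single gene decides, Mt2A. That gene did not pass without Air rat 132, Air rat 138 or PH3 rat 141. In heart the real split stood alone at 1 h (7 genes, highest other 1), 3 h (32, highest other 2) and 6 h (363, highest other 1). In kidney it stood alone at 3 h (14, highest other 0), 6 h (17, highest other 1) and 24 h (2, highest other 1). It did not in kidney at 1 h, where 3 splits were as large as the real 30 genes and the highest other gave 2263. In liver the real split stood alone (32, highest other 2). With 35 splits the smallest possible share is 1 of 35, and the shares were not adjusted over the comparisons. A real split that stands alone therefore does not exclude chance. In lung, 35 of 35 splits were as large at 24 h (0, highest other 0) and at 1 week (0, highest other 3344).

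The splits that gave 2683, 2263 and 3344 genes point to a structure of the samples in brain at 24 h, kidney at 1 h and lung at 1 week. In these groups the main axis held 54.8%, 66.8% and 63.8% of the variance, with arrays of both exposures on either side of 0. In brain at 24 h and kidney at 1 h the 2 lowest scores were those of Air arrays and the 2 highest those of PH3 arrays, so the axis was not free of exposure there. The 3 kidneys with scores above 0 at 1 h, of Air rat 96 and PH3 rats 109 and 116, also had the lowest 3' to 5' differences of beta-actin (2.94 to 3.06 against 3.27 to 3.76) and of GAPDH (0.641 to 0.818 against 1.22 to 1.55). Groups of 2 were not split.

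For the differences between times, 1 of 100 splits was as large in heart (36 genes, highest other 30), and 100 of 100 were in brain (0, highest other 14) and in kidney (0, highest other 2169, again a structure of the samples). For the differences between tissues, 4 of 35 splits were as large at 1 h (7, highest other 1088), 3 at 3 h (18, highest other 669) and 1 at 6 h (41, highest other 23). Chance can thus not be excluded at 1 and 3 h. In heart between times, and at 6 h between tissues, the real split alone reached its count. The shares were not adjusted over the tests, so chance is not excluded there either. For the list tests, 1 of 100 splits was as large (136 calls, highest other 127), and since the other splits had a median of 88 calls, most calls at the preset correlation do not set the real split apart.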

How the results depend on the processing

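Leaving out arrays that stood apart was chosen only after the result was seen, and every other alternative was fixed before the data were examined. The counts moved widely, and the cause was not tested. A further quantile normalization changed 0 of the counts by more than 1.5-fold, and of the 136 list calls it kept 119. The deposited values had already been normalised by quantiles, so this step does not test a different normalization. Without the third of genes with the lowest signal 100 were kept and 27 were not, with the other 9 not tested.

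When only the arrays compared were fitted, 1 gene other than Tmem252 passed in brain at 1 h, and the counts were 0 in brain at 3, 6 and 24 h, 14, 54 and 2 in heart at 3, 6 and 24 h, and 1, 2 and 0 in kidney at 1, 3 and 6 h. They were 161 in liver at 6 h and 520 in lung at 3 h. All probe sets gave 49 in heart at 3 h, 1 in heart at 24 h and 2 for the times of kidney. Without the third of genes with the lowest signal, the counts were 0 in brain at 1 h, 2 in brain at 24 h and 9 between tissues at 3 h.

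Array weights gave 2, 4 and 27 in brain at 1, 3 and 24 h, 751 and 2 in heart at 6 and 24 h, and 113, 103 and 4 in kidney at 1, 6 and 24 h. They gave 91 in liver at 6 h and 2561 in lung at 3 h. For the times they gave 134 in heart, 11 in kidney and 87 in lung, and for the tissues 432 at 1 h and 164 at 6 h.

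With the rat as a block, 4 genes differed between tissues at 3 h. At 1 and 3 h Atf4 did not differ with the block (adjusted p = 0.0506 and 0.0548), and neither did Ccl2 at 6 h (adjusted p = 0.0580). Camera with an estimated correlation called 6 lists instead of 136. Without the arrays of rats 89 and 145 the count in brain at 24 h was 0, and without those of rats 147 and 148 the count in lung at 3 h was 1. Without 6 arrays that stood apart, 118 of the 136 list calls were kept, 17 were not, and the acute phase list of kidney at 3 h turned lower, at adjusted p = 0.573.

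Other probe sets turned the direction of Srebf2 (0.14) in heart at 3 h, Mtf1 (0.15) and Nfkbiz (-0.26) in heart at 6 h, and Per2 (-0.0623) and C1ql3 (0.28) in heart at 24 h. They also turned Sqstm1 (-0.070) and Aif1 (0.25) in kidney at 6 h, Shank2 (0.23) in liver at 6 h and Dact3 (0.0351) in lung at 3 h. Besides these 9, another 32 probe sets kept the direction of the named gene but did not pass where it had. The direction and the outcome of the test were both kept by 33, and 1 passed where the named gene had not.

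Leaving out each array in turn gave ranges of 1 to 4 genes in brain at 1 h (4 without PH3 rat 98, 2 without Air rat 163), 0 to 1 at 3 h, 0 to 2 at 6 h and 0 to 173 at 24 h (173 without Air rat 83). The ranges in heart were 2 to 6 at 1 h, 6 to 85 at 3 h (85 without PH3 rat 105), 134 to 604 at 6 h (134 without PH3 rat 141, 604 without PH3 rat 128) and 0 to 1 at 24 h (1 without Air rat 84). In kidney they were 18 to 38 at 1 h, 5 to 51 at 3 h (51 without PH3 rat 105), 1 to 12 at 6 h (1 without Air rat 132) and 2 to 3 at 24 h. They were 2 to 64 in liver at 6 h (64 without PH3 rat 140), 2 to 72 in lung at 3 h (2 without Air rat 144, 72 without PH3 rat 152), 0 to 0 at 24 h and 0 to 14 at 1 week (14 without Air rat 133).

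For the times, the ranges were 0 to 1 in brain (1 without Air rat 97 at 3 h or PH3 rat 116 at 1 h), 23 to 65 in heart, 0 to 4 in kidney (4 without PH3 rat 115 and 3 without PH3 rat 116 at 1 h, 1 without PH3 rat 105 at 3 h or without Air rat 126 or PH3 rat 128 at 6 h) and 0 to 4 in lung (4 without Air rat 150 at 3 h, 3 without Air rat 133 and 1 without Air rat 185 at 1 week). For the tissues they were 1 to 26 at 1 h (1 without rat 96, 109, 163 or 168, 2 without rat 98, 3 without rat 107, 26 without rat 116), 6 to 50 at 3 h (6 without rat 97 or 120, 8 without rat 108, 9 without rat 122, 50 without rat 105) and 5 to 60 at 6 h (5 without rat 132, 6 without rat 138, 12 without rat 156, 20 without rat 126, 26 without rat 128).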

Other observations

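The 3 PH3 livers of the 3 h group, which have no Air counterpart, held Cyp4a8 at 7.53 ± 0.38, Got1 at 11.55 ± 0.56, Cox10 at 8.74 ± 0.46 and Agxt at 9.86 ± 0.19. The 4 Air livers at 6 h held them at 5.30 ± 0.94, 10.49 ± 0.52, 8.17 ± 0.11 and 9.66 ± 0.25, and no test was made across times. The correlations between tissues below were chosen after the lists were seen and written before they were run, and the test of interferon genes per rat was written only after the result was known.

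Glucocorticoid targets were higher in 15 of 16 comparisons, which share rats between tissues, at the preset correlation and in 1 of them, heart at 1 h, with an estimated correlation. A factor in blood that reaches all tissues of a rat could cause such a pattern. Over the 23 rats with brain, heart and kidney arrays at 1, 3 and 6 h, the rat's own deviation in the list from its group mean correlated between tissues with a mean Pearson r of 0.51 (permutation p = 0.00378, mean Spearman rho 0.41). Of 1000 random lists of 26 genes 7 had a mean r as high. Members of a random list need not vary together, so this count cannot tell a factor in blood from another source of shared variation. In a family of 6 pairs, heart and kidney gave r = 0.62 (permutation p = 0.0280, adjusted p = 0.0841), rho = 0.51 (permutation p = 0.0424) and r = 0.51 without the 2 farthest rats. The pairs with brain did not pass, at r = 0.49 with heart (permutation p = 0.103) and r = 0.41 with kidney (permutation p = 0.185). The mean over the pairs is consistent with a shared factor such as corticosterone in blood, as a hypothesis that no single pair settled and that deviations within a group cannot tie to exposure.

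Interferon-stimulated genes were lower as a list in brain, heart, kidney and liver at 6 h at the preset correlation, with adjusted p = 0.0585, 0.352, 0.102 and 0.579 with an estimated correlation. At the preset correlation the list was called lower in 6 of the 16 comparisons, so such calls were not confined to 6 h. The rats' deviations in this list correlated between tissues with a mean r of 0.53 (permutation p = 0.000850). Of 1000 random lists of 23 genes, 4 had a mean r as high, a count with the same limit as for the glucocorticoid targets. Heart and kidney gave r = 0.75 (permutation p = 0.00172, adjusted p = 0.0103 in the family of 6), rho = 0.73 (permutation p = 0.00197) and r = 0.70 without the 2 farthest rats, and the pairs with brain did not pass (r = 0.47, permutation p = 0.0743 with heart, and r = 0.37, permutation p = 0.154 with kidney). Averaged over heart, kidney and liver of each rat, the list was 0.49 lower in 4 PH3 than in 4 Air rats at 6 h (exact two-sided p = 0.0286, the smallest possible), which restates the list calls that prompted it and adds no separate evidence. The correlation between heart and kidney is consistent with a factor that acted on both tissues of a rat, as a hypothesis.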
